A study of Mus musculus with 6 samples.

How the data were processed

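Gene expression was measured by RNA sequencing of the medial prefrontal cortex, a frontal region of the cerebral cortex, of C57BL/6 mice, in 3 control libraries and 3 libraries of mice kept alone for 3 weeks after weaning. The labels give an age of 6 weeks for every sample, whereas the text on the series' design gives 7 weeks, and the 2 ages were not reconciled. Nothing in the labels says that the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which could be technical. Total RNA was sequenced on a BGISEQ-500 instrument with reads of 50 bases, per the labels' protocols. The labels give neither the sex of the mice nor a sequencing batch or date.

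The authors deposited 1 table per library with an expected count, an FPKM value and a length for each gene. An expected count is an estimate of the reads that came from a gene, in which a read that matches several genes is shared out between them. The expected count need not be whole, and it was not normalized in the deposited tables. The deposited FPKM values are expected counts scaled for the length of the gene and the size of the library (FPKM), as named per the file headers. HISAT, Bowtie2, RSEM and the mouse genome build mm10 are named per the submitters' processing notes, without versions, order or settings. The transcripts listed beside each gene are RefSeq transcripts, per the file headers. Whether the counting used strand is not given in the sources used here, so reads of a gene and of an overlapping gene on the other strand were treated as not separable. A further table of FPKM values for the whole series was not used here, because its 6 columns carry codes that no sample label gives.

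Each table listed between 18131 and 18312 genes, and genes missing from a table were set to 0. The single entry per table without a gene symbol held at most 0.00095% of the reads and was left out. The remaining expected counts summed to between 18226448 and 18606573 per library over 19943 genes. Of these gene identifiers 19899 matched the RefSeq annotation of the assembly GRCm38.p6, from which symbols and coordinates were taken, which also replaced 26 symbols that had been turned into calendar dates. The top 10 genes held between 2.97% and 3.26% of the counts in each library. Every pair of libraries differed by more than counting noise, with a chi-square between 2.89 and 20.36 per gene for genes with at least 20 counts in the pair, so no library was counted as a repeat of another.

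Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr at its minimum count of 10 and minimum total of 15, which left 15169 genes and removed 4774. Library sizes were scaled with TMM factors between 0.991 and 1.012. The quasi-likelihood F-test compared isolated with control libraries without covariates, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are given as log2 of isolated over control, with a standard error derived from the fold change and the F statistic, and 95% intervals from the t distribution. Levels are TMM-normalized CPM, counts scaled to a common library size, given as mean ± SD over the 3 libraries of a group. Depths of this size give low-count genes wide errors, and intervals cover these libraries only.

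Before the data were examined, 32 gene lists were fixed from general knowledge of the tissue. They hold activity-induced immediate early genes, myelin and mature oligodendrocyte genes, oligodendrocyte progenitor genes, and markers of microglia, astrocytes, vascular cells, meningeal fibroblasts, choroid plexus and ependyma, striatal projection neurons, olfactory bulb and migrating neuroblasts, red blood cells, interneurons, and upper-layer and deep-layer cortical neurons. The others hold glutamate receptor and postsynaptic, GABA receptor, synaptic vesicle, ion channel, stress and social peptide, monoamine and acetylcholine, glucocorticoid response, neurotrophin and neuregulin, perineuronal matrix, interferon response, inflammation, cholesterol synthesis, circadian clock, heat shock and endoplasmic reticulum stress, nuclear respiratory chain, ribosomal protein, mitochondrially encoded and sex-linked genes. The red blood cell and sex-linked lists served as checks and were not tested as sets. The mitochondrially encoded list had 0 members among the genes analysed here, which left 29 lists. Each was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2. Camera compares the mean test statistic of a list's members, in which each difference is weighed against its spread, with that of the other genes. A list is called ranked upward or downward below by the direction of this comparison, which uses no ranks of genes. The preset correlation of camera between genes was 0.01, and p-values were adjusted over the 29 lists. Beside it stand camera with the correlation estimated from the data and the rotation test fry, which asks whether the members move one way on balance.

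The genes named were also set by a rule fixed beforehand: in each direction the 12 genes with the largest change among those past the threshold, filled up, where fewer passed, with the genes of smallest p, in both cases with a mean of at least 1 CPM, no overlap between the groups and a proper gene name. Added to these were the 4 members with the smallest p of each list and 11 genes of prior interest (Oxtr, Bdnf, Crh, Pvalb, Sst, Mbp, Nrg1, Fos, Arc, Cx3cr1 and Gfap). Other genes named were chosen after their values were seen. Of the genes the rule picked, 1 was left out and is not reported here. The other 152 were examined under the alternatives below, and the text gives values for a part of them. For these 152 genes, exons were compared with those of other genes in the GENCODE vM21 annotation, and 15 shared at least 10% of their exon bases with another gene.

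The gene test and the set test were tested on simulated data with the means, dispersions and library sizes of the 15169 genes of this comparison. In 5 simulations with 200 changed genes each, 39.1% of changes of 0.5 in log2 were called, 83% of changes of 1 and 98.2% of changes of 2, and 8.7% of all calls were false. A list raised by 0.5 was called in 5 of 5 simulations, and 2 of 140 tests of unchanged lists gave a call. Genes were simulated independently of each other, whereas members of some real lists moved together. The estimated correlation was 0.97 in the myelin list and 0.39 in the immediate early list. The simulation therefore does not give the rate of false list calls in these data. The shares of changes called hold for 200 changed genes and would be lower with fewer.

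Alternatives fixed beforehand were median-ratio (RLE) scaling, DESeq2 1.42.0, limma-voom, no filter beyond 1 count, a stricter filter of 1 CPM in 3 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes of mean FPKM of at least 1, log2(FPKM + 1) without that filter, the replicate number as a block, leaving out each library, an adjusted p of 0.1, a minimum log2 change of 1, and the other set tests. After the data were examined, 2 further settings were added: the level of the striatal list as a covariate, and the removal of control 2 and isolated 3. The correlations (Pearson r) of list levels with the striatal and myelin lists over the 6 libraries were also computed then. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.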

Results

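The series compared the medial prefrontal cortex of mice housed alone after weaning with that of control mice, to ask how early social isolation alters gene expression there. There were 3 control libraries and 3 isolated libraries, named here control 1 to 3 and isolated 1 to 3. Depth was even, at 18226448 to 18544306 expected counts in the control libraries and 18390902 to 18606573 in the isolated libraries. The male-specific gene Ddx3y lay between 50.1 and 55.5 CPM in all 6 libraries and Xist, which is expressed from the inactive X chromosome, between 0.426 and 0.871 CPM. Red blood cell genes were present in both groups, with Hbb-bs at 71.4 ± 8.96 CPM in control and 82 ± 28.3 CPM in isolated libraries (SD, n = 3).

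The largest differences between the libraries lay within the groups, in genes of striatal projection neurons, the main cell type of the neighbouring striatum. The dopamine receptor gene Drd2 stood at 68.2 CPM in control 2 and 50.2 CPM in isolated 3, but at 19.1 CPM in control 1, 0.605 CPM in control 3, 6.78 CPM in isolated 1 and 6.36 CPM in isolated 2. Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, ranged from 108 CPM in control 3 to 834 CPM in control 2. The mean level of the 15 striatal markers differed 13.8-fold between the highest and the lowest library, both of them controls. The first principal component held 50.6% of the variance, and 13 of its 50 leading genes were striatal markers. Both groups held libraries with high and with low striatal levels, so the list did not separate them: its members were on average 0.43 lower in isolated libraries on the log2 scale (camera adjusted p = 0.49). Without control 2 the list stood higher in isolated libraries (mean 0.81), without isolated 3 or control 3 it stood lower (-1.69 and -0.92), each past the threshold at the preset correlation. With an estimated correlation these 3 settings gave p = 0.44, 0.37 and 0.31 by camera of limma. Without isolated 1 or isolated 2 its mean was -0.07.

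**Figure D1:**
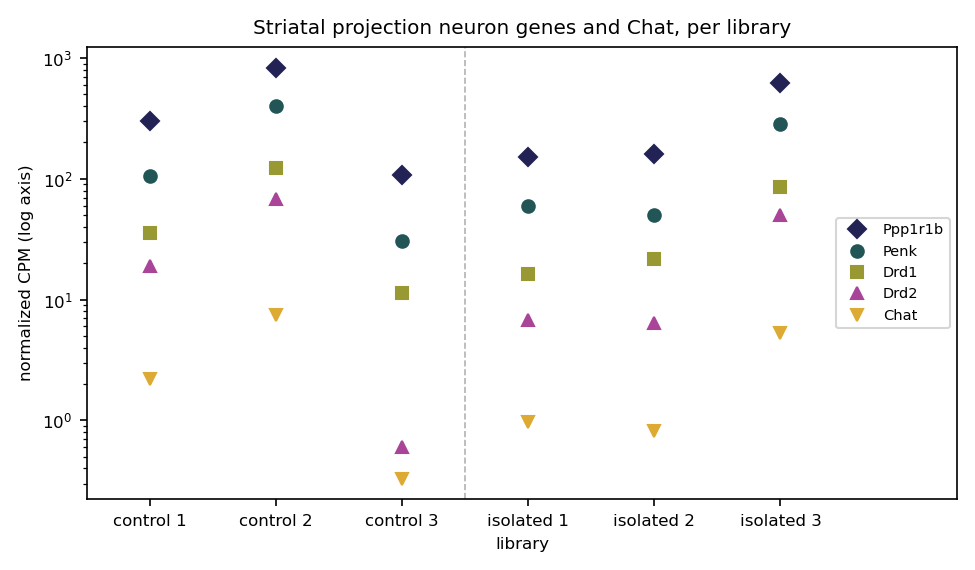
Normalized CPM on a log axis of 4 genes of striatal projection neurons (Ppp1r1b, Penk, Drd1, Drd2) and of the cholinergic gene Chat in each of the 6 libraries, with 1 point per gene and library. Control 2 and isolated 3 hold the highest values of each gene, and the groups overlap.

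Fkbp5 had the smallest p with edgeR on all 6 libraries. This gene encodes a co-chaperone that restrains the glucocorticoid receptor and is itself induced by glucocorticoids. It was measured at 33.3 ± 1.21 CPM in control and 49.3 ± 5.52 CPM in isolated libraries (SD, n = 3), a log2 difference of 0.57 with a standard error of 0.09 and a 95% interval from 0.36 to 0.77. All 3 isolated libraries (45, 47.4 and 55.5 CPM) lay above all 3 control libraries (32.5, 32.7 and 34.7 CPM). Fkbp5 lies on chromosome 17 from 28398753 to 28486149 (GRCm38, Entrez gene 14229). With edgeR's quasi-likelihood test its unadjusted p was 0.00027, and its p adjusted over 15169 genes by the Benjamini-Hochberg method was 0.999. Adjusted over the list alone, the 19 measured glucocorticoid response genes, its p was 0.0051. This adjustment does not count the other lists. Fkbp5 also had the smallest p in 9 of 17 alternative settings and another gene in 8, among them Egr2 without control 3 and Capn11 without isolated 1.

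No gene passed the threshold in either direction with edgeR: 0 were higher and 0 were lower at an adjusted p under 0.05, and 535 had an unadjusted p under 0.05 (231 higher, 304 lower), fewer than the 758 that chance alone gives on average. DESeq2 called 1 gene, Fkbp5, with an adjusted p of 0.0088 (331 genes at an unadjusted p under 0.05), and limma-voom called 0 (536). Values of the 2 groups did not overlap for 1342 genes, or 8.8%, where chance gives 10%. In simulated data of the same depth and spread, 39.1% of changes of 0.5 in log2 were recovered and 83% of changes of 1, so changes of the size seen for Fkbp5 would often be missed. Each simulation held 200 changed genes and no shared striatal difference between libraries. With fewer changed genes the adjusted threshold is harder to pass, so these shares may be too high for the real comparison.

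The genes with the next smallest p did not pass either, although their groups were apart in all 6 libraries. Among those higher in isolated libraries, Sema5a, a semaphorin that guides axons, stood at 62.1 ± 3.68 CPM in control and 81.1 ± 7.7 CPM in isolated libraries (log2 difference 0.39, SE 0.08). The adhesion molecule gene Dscaml1 was at 66.5 ± 0.983 and 80 ± 5.16 CPM, and Frat1, which binds the kinase GSK-3 in Wnt signalling, at 11.2 ± 0.394 and 14.3 ± 0.313 CPM. The histone H3.3 gene H3f3b was at 99.8 ± 4.89 and 116 ± 1.32 CPM, and the DNA crosslink repair gene Fancd2 at 3.25 ± 0.184 and 4.8 ± 0.279 CPM. Pskh1, Pkp2 and Ppp1r10 were higher by 0.45, 0.57 and 0.21 in log2. The remaining 3 were scarce and rested on few counts: Capn11 (0.2 ± 0.138 and 1.86 ± 1.11 CPM), Lbp (0.908 ± 0.106 and 2.42 ± 1.14 CPM) and Tekt1 (0.527 ± 0.135 and 1.56 ± 0.688 CPM), each highest in isolated 3. Without control 2 and isolated 3 the log2 difference of Lbp was 0.93 in place of 1.41, and that of Tekt1 was 0.99 in place of 1.56. On log2(FPKM + 1) without a filter the differences of Capn11, Lbp and Tekt1 were 0.65, 0.5 and 0.59.

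In the other direction none passed either. Unc5d, a receptor for the guidance cue netrin, was at 64.1 ± 2.41 CPM in control and 52.3 ± 1.4 CPM in isolated libraries (log2 difference -0.29, SE 0.05, edgeR adjusted p = 0.999). Nptxr, a pentraxin receptor that gathers AMPA receptors at synapses, was at 575 ± 26.7 and 448 ± 35.9 CPM. Ntng2, a membrane-bound netrin, was at 34.9 ± 4.67 and 25.1 ± 1.03 CPM. The interleukin 10 receptor gene Il10ra was at 7.61 ± 1.16 and 4.91 ± 0.0242 CPM. Kitl, which encodes stem cell factor, stood at 67.3 ± 1.52 and 57.8 ± 1.2 CPM, and the neuropeptide gene Cartpt at 5.06 ± 1.38 and 2.66 ± 0.336 CPM. Rasl10a, Nol4l, Gpr153, Tmtc3, Lrrc32 and Samd3 were lower by log2 differences of -0.28, -0.28, -0.28, -0.26, -0.58 and -1.12. Exons of Npcd cover 17.2% of the exon bases of Nptxr and those of a neighbouring gene 14% of Ntng2, on the same strand, so part of these reads is uncertain.

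**Figure D2:**
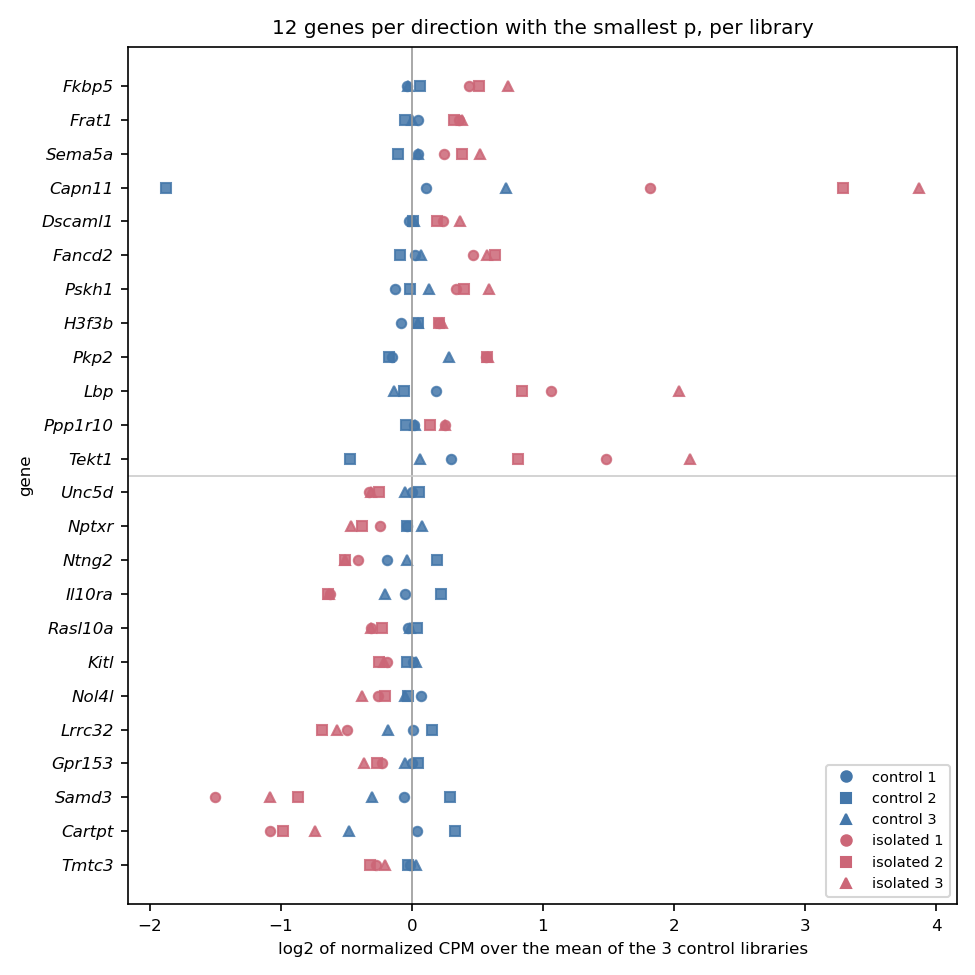
Level of the 12 genes per direction with the smallest p and groups apart, 1 gene per line, as log2 of normalized CPM over the mean of the 3 control libraries, with 1 point per library. The 3 isolated libraries lie to the right of the controls for the upper 12 genes and to the left for the lower 12, which is how these genes were chosen, and none passed edgeR's adjusted threshold.

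Glucocorticoid response genes stood higher as a list in isolated libraries: 14 of 19 measured members were higher, 5 of them at an unadjusted p under 0.05 (camera adjusted p = 8e-04, and adjusted p = 0.46 with an estimated correlation). Beside Fkbp5, the lipid droplet gene Plin4 was at 4.73 ± 2.99 CPM in control and 13.1 ± 4.91 CPM in isolated libraries, the metallothionein gene Mt2 at 42.1 ± 2.04 and 49.8 ± 5.04 CPM and the sulfotransferase gene Sult1a1 at 5.74 ± 0.93 and 7.66 ± 0.632 CPM. Zbtb16 was higher by 0.76 (SE 0.3), whereas the clock gene Per1, also in this list, had a log2 difference of -0.5. No member but Fkbp5 passed when adjusted over the list alone. Over the 6 libraries the mean level of this list moved with that of the myelin list below (r = 0.95). The mean log2 difference of the list was 0.19, and it was 0.14 without control 3 (camera adjusted p = 0.18), 0.1 without isolated 3 (0.094), 0.06 without control 2 and isolated 3 (0.053) and 0.3 without control 1. An antisense gene covers 73.5% of the exon bases of Mt2, whose reads could not be separated from it.

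Myelin and mature oligodendrocyte genes also stood higher: 22 of 22 members had a higher mean in isolated libraries, by 0.38 in log2 on average (camera adjusted p = 7.5e-09, and adjusted p = 0.46 with an estimated correlation). With edgeR 0 members had an unadjusted p under 0.05. Myelin basic protein, Mbp, was at 1600 ± 456 CPM in control and 2160 ± 796 CPM in isolated libraries. Mog was at 40.5 ± 10.9 and 56.3 ± 15.9 CPM and the gap junction gene Gjb1 at 8.02 ± 1.73 and 11.6 ± 3.65 CPM. The level rested on single libraries: isolated 3, which also held high striatal levels, lay 0.67 above the mean of the 6 libraries and control 3 lay 0.5 below it (-0.5). Without isolated 3 the mean difference was 0.09, without control 1 it was 0.61, without control 3 it was 0.24, and without control 2 and isolated 3 it was 0.04 (camera adjusted p = 0.1). The oligodendrocyte progenitor list, in which 10 of 14 members were higher, did not pass (camera adjusted p = 0.052), with Olig2 at 20 ± 1.72 and 25.7 ± 6.48 CPM. Its mean of 0.12 was -0.02 without isolated 3, 0.05 without control 3 and 0 without control 2 and isolated 3.

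Markers of deep and upper cortical layers went in opposite directions. The mean level of the deep-layer list moved with that of the striatal list over the 6 libraries (r = 0.85), although not every member did. The deep-layer difference did not shrink with the striatal level as a covariate (mean 0.16, camera adjusted p = 4.5e-06, and p = 0.026 with an estimated correlation, not adjusted over the lists) or without control 2 and isolated 3 (mean 0.13, camera adjusted p = 0.00092, and p = 0.13 with an estimated correlation). Of the deep-layer markers 14 of 18 were higher in isolated libraries (camera adjusted p = 0.0053, and adjusted p = 0.46 with an estimated correlation). Among them were the layer 5 regulator Fezf2 at 29.7 ± 7.91 and 42.1 ± 6.72 CPM, Etv1 at 64.4 ± 9.83 and 83.1 ± 11 CPM and Crym at 37 ± 5.87 and 50.3 ± 7.77 CPM. Within each group Fezf2 was lowest in the library with the highest striatal level, at 20.9 CPM in control 2 and 35.6 CPM in isolated 3. The same held for Etv1 (54.8 and 75.1 CPM) and Npr3 (9.26 and 13.9 CPM), whereas Crym was lowest in control 1 and isolated 1 (31.1 and 42.6 CPM). Of the upper-layer markers 9 of 14 were lower (camera adjusted p = 0.026, and adjusted p = 0.46 with an estimated correlation). Among them were Rorb at 54.6 ± 7.89 and 39.7 ± 5.61 CPM, Cux1 at 137 ± 18 and 112 ± 4 CPM and Calb1 at 105 ± 13.7 and 88.9 ± 2.43 CPM. The mean log2 difference of the deep-layer list was 0.13, against 0.03 without control 3 (camera adjusted p = 0.25), -0.01 without isolated 3 (0.19), 0.27 without control 2 and 0.21 without isolated 1. That of the upper-layer list was -0.11, against -0.04 without control 1 (camera adjusted p = 0.22), -0.09 without control 3 (0.19), -0.05 without isolated 3 (0.41), -0.18 without control 2 and -0.19 without isolated 1. On log2(FPKM + 1) without a filter it was -0.08 (camera adjusted p = 0.053).

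Immediate early genes, which neurons switch on within minutes of activity, stood lower in isolated libraries: 23 of 28 members were lower, by a mean log2 difference of -0.42 (camera adjusted p = 3.1e-06, and adjusted p = 0.46 with an estimated correlation). The transcription factor genes Egr2 (10.8 ± 4.92 CPM in control and 4.78 ± 0.61 CPM in isolated libraries) and Nr4a2 (48.7 ± 25.4 and 23.9 ± 5.26 CPM) were lower in all 3 isolated libraries than in any control. Fos was at 23.5 ± 10.1 and 13.7 ± 2.41 CPM, and Arc, whose protein acts in synaptic plasticity, at 250 ± 231 and 98.2 ± 40.1 CPM, with overlapping groups. Control 1 lay 0.54 above the mean of the 6 libraries. Without it the mean difference was -0.21 and the list no longer passed (camera adjusted p = 0.057). Without control 3, the lowest control, the mean difference was -0.6. The circadian clock list, which shares Per1 with this one, was lower in 14 of 16 members (camera adjusted p = 0.0021, and adjusted p = 0.46 with an estimated correlation). In it Arntl stood at 35.9 ± 1.64 and 31.5 ± 1.86 CPM and Nr1d1 at 209 ± 32.4 and 176 ± 12.4 CPM. Its mean difference of -0.12 was -0.04 without control 1 (camera adjusted p = 0.23) and -0.09 without isolated 2 (0.051).

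Markers of 3 non-neuronal cell types stood slightly lower in isolated libraries. Vascular markers were lower in 18 of 20 members by a mean log2 difference of -0.12 (camera adjusted p = 8.9e-05, and adjusted p = 0.46 with an estimated correlation). Vtn, which marks pericytes, was at 56.3 ± 6.24 and 44.3 ± 2.66 CPM and the endothelial gene Flt1 at 66.5 ± 1.24 and 61 ± 2.67 CPM. Microglial markers were lower in 17 of 20 members (camera adjusted p = 0.0025, and adjusted p = 0.46 with an estimated correlation). The fractalkine receptor gene Cx3cr1 was at 46.9 ± 4.27 and 41 ± 0.758 CPM. Astrocyte markers were lower in 13 of 16 members (camera adjusted p = 0.0098, and adjusted p = 0.46 with an estimated correlation). The water channel gene Aqp4 was at 101 ± 16.6 and 81.8 ± 3.3 CPM and the glutamate transporter gene Slc1a2 at 3060 ± 124 and 2800 ± 112 CPM. The mean difference of the microglial list, -0.07, was -0.05 without isolated 1 (camera adjusted p = 0.056), and that of the astrocyte list, also -0.07, was -0.05 without control 1 (0.14) and -0.06 without isolated 1 (0.066). The vascular mean was -0.06 without control 2 and -0.03 without control 2 and isolated 3 (camera adjusted p = 0.16).

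Of the 26 inflammation genes fixed beforehand 14 were tested, and 10 of these were lower (camera adjusted p = 0.018, and adjusted p = 0.46 with an estimated correlation). The NF-kB inhibitor gene Tnfaip3 was at 8.72 ± 0.22 and 6.49 ± 0.817 CPM, Icam1 at 2.5 ± 0.406 and 1.69 ± 0.331 CPM and Tlr4 at 1.98 ± 0.38 and 1.35 ± 0.0421 CPM. Their mean log2 difference was -0.16, against -0.05 without control 2 (camera adjusted p = 0.18), -0.15 without control 1 (0.11), -0.17 without isolated 3 (0.1), -0.06 without control 2 and isolated 3 (0.37) and -0.25 without control 3. On log2(FPKM + 1) it was -0.08 (camera adjusted p = 0.12), on the same scale without a filter -0.06 (0.01), and on counts without a filter -0.39 (0.0045). In all, 3 of 29 lists were called higher and 7 lower with the preset correlation, and 0 with an estimated correlation or with fry.

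**Figure D3:**
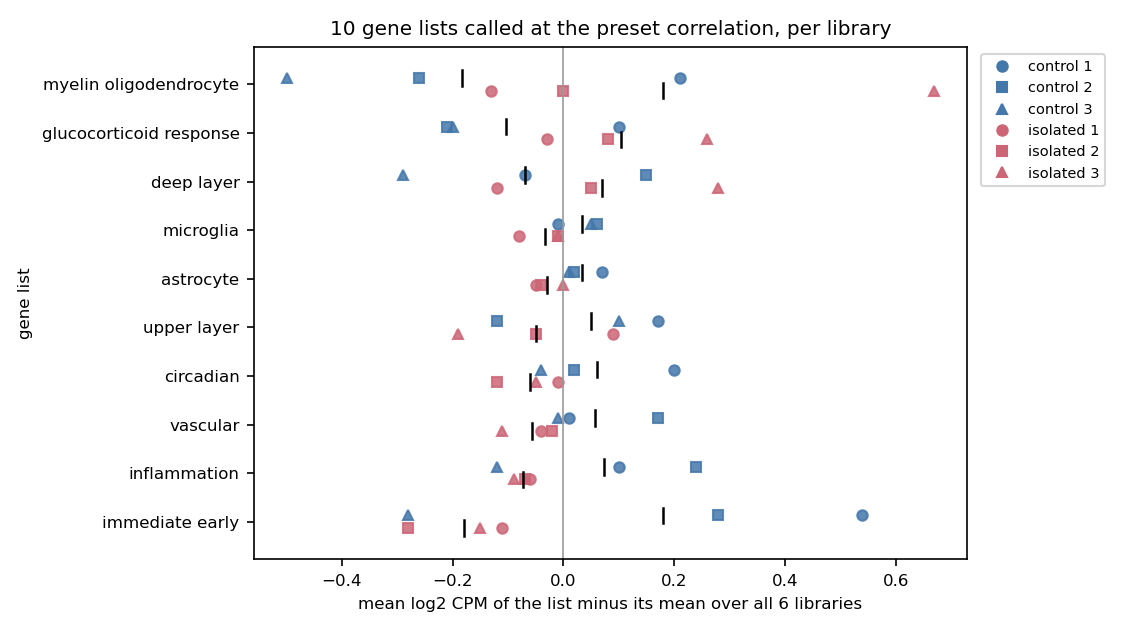
Mean log2 CPM of each of the 10 lists called at the preset correlation, as a deviation from its mean over the 6 libraries, with 1 point per library and a black tick at each group's mean. The groups overlap in most of these lists, not in the vascular and astrocyte lists, and isolated 3 in the myelin list (0.67) and control 1 in the immediate early list (0.54) stand farthest out.

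Genes of the stress and social peptide systems were lower in 16 of 22 members, which did not pass (camera adjusted p = 0.099). This list holds the striatal genes Penk and Tac1 and moved with the striatal list over the 6 libraries (r = 0.93), and its mean of -0.12 was 0.15 without control 2 and 0.07 without a filter. The oxytocin receptor gene Oxtr was at 7.07 ± 1.51 CPM in control and 5.18 ± 0.455 CPM in isolated libraries and the glucocorticoid receptor gene Nr3c1 at 145 ± 4.61 and 131 ± 4.86 CPM, both with the groups apart. The corticotropin-releasing hormone gene Crh was at 4.58 ± 0.18 and 3.75 ± 0.82 CPM, and each had an edgeR adjusted p of 0.999. Neurotrophin and neuregulin genes were lower in 9 of 17 members (camera adjusted p = 0.38, with the list ranked upward against a median of -0.04 and a mean of -0.01). This list moved with the striatal list over the 6 libraries (r = 0.99), and its mean was 0.23 without control 2 and -0.31 without isolated 3. In that list Bdnf was at 26.5 ± 1.71 and 25.4 ± 8.46 CPM, Nrg1 at 5.79 ± 1.22 and 5.62 ± 1.21 CPM and the Bdnf receptor gene Ntrk2 at 717 ± 47.2 and 791 ± 19.5 CPM. Interneuron markers were higher in 11 and lower in 11 of 22 members (camera adjusted p = 0.99), with Pvalb at 48.7 ± 15.8 and 45.6 ± 4.11 CPM and Sst at 136 ± 7.41 and 144 ± 9.56 CPM. The astrocyte filament gene Gfap was at 81.2 ± 11.7 and 76.8 ± 13.6 CPM.

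Synaptic and channel genes did not pass as lists with all 6 libraries. Glutamate receptor and postsynaptic genes were lower in 23 of 32 members (camera adjusted p = 0.17), with the NMDA receptor gene Grin2b at 63.9 ± 0.343 and 56.8 ± 1.29 CPM, and GABA receptor genes in 11 of 16 (0.17), with Gabra2 at 31.2 ± 3.36 and 25.6 ± 1.97 CPM. Over the 6 libraries the levels of both lists moved against that of the myelin list (r = -0.95 and -0.73). Synaptic vesicle genes were lower in 14 of 26 members (camera adjusted p = 0.86), ion channel genes in 23 of 35 (0.38) and perineuronal matrix genes in 10 of 14 (0.22). Monoamine and acetylcholine genes were lower in 16 of 32 members (camera adjusted p = 0.42, ranked upward with a median of 0.01 and a mean of -0.05), with Chrm4 at 67.9 ± 24.8 and 47.5 ± 7.87 CPM. They include the striatal genes Drd1 and Drd2 and moved with the striatal list (r = 0.98), and their mean was 0.13 without control 2 and -0.18 without isolated 3. Of the 16 choroid plexus and ependymal markers fixed beforehand 8 were tested. In this list 6 of 8 members were higher (camera adjusted p = 0.11), with the transthyretin gene Ttr at 1.66 ± 0.591 and 3.12 ± 0.793 CPM. The mean of this list, 0.3, was 0.58 without control 2, 0.8 without a filter, 0.47 with the stricter filter and -0.02 without isolated 3. Meningeal fibroblast markers were lower in 9 of 14 members (camera adjusted p = 0.27) and olfactory and neuroblast markers in 6 of 12 (0.66, ranked upward with a median of 0.04 and a mean of -0.02). The choroid plexus, perineuronal and olfactory lists also moved with the striatal list (r = 0.87, 0.86 and 0.92).

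Interferon response genes were lower in 15 of 20 members, cholesterol synthesis genes in 15 of 24 and heat shock and endoplasmic reticulum stress genes in 20 of 26, each with a camera adjusted p of 0.1. Hspa1b, with a near-identical copy in Hspa1a that makes its counts uncertain, was at 16.1 ± 8.48 and 9.94 ± 0.637 CPM. Nuclear respiratory chain genes were lower in 46 of 82 members (camera adjusted p = 0.42) and ribosomal protein genes higher in 46 of 78 (0.38), with mean log2 differences of -0.01 and 0.01. Among all 687 list members tested, 34 had an unadjusted edgeR p under 0.05, close to the share of 0.05 that chance gives. Over all 15169 tested genes the share was lower, at 3.53%. Only Fkbp5 passed when adjusted over its list alone, an adjustment that does not count the other lists.

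Several of the 19 lists that did not pass did so at the preset correlation in other settings, while with an estimated correlation 0 lists passed in any setting. Without control 2 the choroid plexus (camera adjusted p = 0.019), oligodendrocyte progenitor (0.01) and ribosomal (0.023) lists passed as higher, and the ion channel (0.019), synaptic vesicle (0.025) and heat shock (0.0092) lists as lower. Without control 3 the cholesterol (0.043) and heat shock (0.0035) lists passed as lower. Without isolated 1 the oligodendrocyte progenitor (0.002) and ribosomal (0.0071) lists passed as higher, and the fibroblast (0.00023), interferon (0.048) and heat shock (0.033) lists as lower. Without isolated 2 the choroid plexus (0.024) and oligodendrocyte progenitor (0.011) lists passed as higher and the cholesterol list (0.0021) as lower. Without control 2 and isolated 3 the ion channel list passed as lower (0.029) and the fibroblast list as higher (0.00037). With the stricter filter and with the striatal covariate the choroid plexus (0.036 and 0.041) and oligodendrocyte progenitor (0.045 and 0.016) lists passed as higher and the stress and social peptide list (0.049 and 0.041) as lower. Without a filter the choroid plexus list passed on counts (0.0045) and on FPKM (0.018).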

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

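The striatal covariate and the removal of control 2 and isolated 3 were chosen after the data had been seen. Over all alternatives 2514 of 2545 values of the 152 genes named by rule and 424 of 519 values of the 29 lists kept their direction and their side of the threshold, with 30 reversals in 17 genes and 25 in 7 lists. For the genes this count says little. None passed with edgeR, so keeping the side of the threshold meant staying uncalled. In addition, 24 genes were chosen for groups that were apart, so their direction could hardly turn when a library was left out. Of their values 395 of 396 kept both. DESeq2 called 1 gene higher, Fkbp5, whose log2 difference ran from 0.47 to 0.63 over the alternatives, and the other settings called 0 genes (edgeR with all libraries and limma-voom had 535 and 536 at an unadjusted p under 0.05). DESeq2 has no set test, so it gave no value for lists. Lists called higher and lower, 3 and 7, were 0 and 0 with an estimated correlation and 0 and 0 with fry. The stricter filter and the striatal covariate each called 5 lists higher. Leaving out 1 library at a time called 1 to 7 lists higher and 2 to 9 lower. The replicate number as a block called 0 genes (331 at an unadjusted p under 0.05) and 10 of the same lists. Deviations from the group mean over all genes did not move together in libraries of the same number (r = 0.03, -0.27 and -0.49). The r of control 2 with isolated 3, both high in striatal genes, was 0.44. Because the striatal level weighs on these r values, they cannot show whether the numbers pair animals. For lists, the direction is that of camera's ranking, which can differ in sign from the mean log2 difference printed beside it. Without control 2 and isolated 3 the direction turned for Olig1 (0), Col6a3 (-0.22), Slc6a13 (0.01), Foxj1 (-0.1), Bdnf (0.13) and the fibroblast (0.22), olfactory (-0.03) and interneuron (0.01) lists. Hba-a2 turned with limma-voom (-0.02) and with log2(FPKM + 1), log2(FPKM + 0.1), unfiltered FPKM, the block and the covariate (-0.01 each). The olfactory list, ranked upward at a mean of -0.02, was ranked downward with log2(FPKM + 1) (mean -0.03) and log2(FPKM + 0.1) (-0.06). The interneuron list turned with the stricter filter (0), log2(FPKM + 1) (0.01), log2(FPKM + 0.1) (0.02) and the covariate (0.01). With 1 library left out, directions turned within these ranges: Bcas1 0 to 0.56, Col6a3 -0.11 to 1.25, Foxj1 -0.02 to 1.05, Scn4b -1.15 to 0.36, Adora2a -2.75 to 1.08, Syndig1l -2.6 to 0.84, Hbb-bs -0.08 to 0.42, Alas2 -0.29 to 0.41, Hba-a2 -0.2 to 0.26, Uty -0.15 to 0.03, Kdm5d -0.02 to 0.07, Bdnf -0.3 to 0.18, Pvalb -0.29 to 0.18, Nrg1 -0.2 to 0.11 and Gfap -0.23 to 0.02. The ranking turned within these ranges of the mean for the fibroblast (-0.25 to 0.1), striatal (-1.69 to 0.81), olfactory (-0.27 to 0.22), interneuron (-0.04 to 0.05), synaptic vesicle (-0.04 to 0.01), heat shock (-0.19 to 0.01) and ribosomal (-0.01 to 0.04) lists. The mean alone crossed 0 for the neurotrophin (-0.31 to 0.23), monoamine (-0.18 to 0.13), stress and social peptide (-0.36 to 0.15), perineuronal (-0.08 to 0.01), oligodendrocyte progenitor (-0.02 to 0.19), choroid plexus (-0.02 to 0.58) and deep-layer (-0.01 to 0.27) lists. Values near 0 turn with small shifts, and the cause was not tested. Scarce genes depend on the scale: on unfiltered log2(FPKM + 1) Capn11, Fancd2, Lbp, Tekt1 and Samd3 differed by 0.65, 0.26, 0.5, 0.59 and -0.44, and with the filter Il10ra and Lrrc32 differed by -0.39 and -0.34.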

Other observations

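The cilium families below, the tests of isolation for the striatal genes, of striatal tissue for Fkbp5 and of both explanations for the immediate early genes, and the counts of splits for genes and lists were chosen after the results had been seen. Motile cilium genes, which build the beating cilia of ependymal cells, were mostly higher in isolated libraries. In 6 gene families taken by symbol (Dnah, Dnaaf, Cfap, Drc, Tekt and Rsph), 33 of 42 tested genes were higher and 9 lower, with a median log2 difference of 0.19 and a mean of 0.38. Because these families were picked from the same data, with Tekt1 already among the genes named as higher, no test of them as a set is given. Cfap45 stood at 1.09 ± 0.194 CPM in control and 1.91 ± 0.161 CPM in isolated libraries (SD, n = 3), the axonemal dynein gene Dnah9 at 3.98 ± 0.569 and 6.73 ± 2.11 CPM, Cfap65 at 5.87 ± 1.1 and 8.32 ± 1.11 CPM and Drc7 at 0.308 ± 0.124 and 1.27 ± 0.858 CPM. With edgeR 0 of the genes passed after adjustment over all genes. The 3 isolated libraries lay 0.03, 0.04 and 0.42 above the 6-library mean of these genes and the controls below it (-0.12, -0.23 and -0.15). Isolated 3 also held the highest level of the ependymal regulator Foxj1 (12.1 CPM, against 2.8 to 6.43 CPM in the other libraries) and of the choroid plexus and ependymal list (0.57 above the 6-library mean). Over the 6 libraries the level of the cilium genes moved with that of the myelin list (r = 0.83). Without isolated 3 the mean difference of the cilium genes was 0.21 and the median 0.12.

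Striatal genes differed between libraries of the same group, with control 2 and isolated 3 highest (1.91 and 1.47 above the 6-library mean of the list) and control 3 lowest (-1.88). Isolation as the cause is argued against by the overlap of the groups: their ranges of the list's mean log2 CPM left a gap of -2.8, and the highest and the lowest library were both controls. A candidate explanation is tissue of the striatum or nearby basal forebrain in the dissected piece. It predicts genes of cholinergic and other subcortical neurons in the same libraries, and the mean of Chat, Slc18a3, Isl1 and Lhx8 was at least 1.71 log2 units higher in control 2 and isolated 3 than in any other library. Chat stood at 7.46 and 5.27 CPM there and at 0.33 to 2.22 CPM elsewhere, and a difference between the animals was not tested.

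Fkbp5 was higher in the 3 isolated libraries than in any control. A different share of striatal tissue or of oligodendrocytes as the whole cause is argued against: with the striatal list as a covariate the log2 difference was 0.57 (SE 0.07, edgeR adjusted p = 0.51), and with the myelin list it was 0.48 (SE 0.09, edgeR adjusted p = 0.83). A wider glucocorticoid response stays open: of the 18 other members of that list 13 were higher, with camera p = 0.0017 at the preset correlation and p = 0.22 with an estimated correlation. The level of the whole list moved with that of the myelin list (r = 0.95). Relative to the 6-library mean, control 1 (0.1) lay above isolated 1 (-0.03) and isolated 2 (0.08). The other members were not tested with the myelin level as a covariate. Chance stays open as well. It predicts that another split of the 6 libraries holds a gene with as small a p, and this prediction was met. With 15169 genes tested, a p this small is likely in any split, whether or not isolation raised Fkbp5, so this outcome decides little. The real split gave a smallest p of 0.00027 with edgeR and the lowest of the others was 2e-05. That lowest p came from control 1, control 2 and isolated 3 against the rest, a split that follows the striatal level. Of the 10 splits, the real one included, 5 reached one as small. The 10 splits are too few for a share under 0.05. Isolation may have raised Fkbp5, a hypothesis from a gene picked in these data, which a measurement of Fkbp5 and of corticosterone in other animals would test and which was not tested so here.

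Immediate early genes were lower in isolated libraries as a list at the preset correlation, a call lost with an estimated one (adjusted p = 0.46 with an estimated correlation). A different share of striatal tissue stays open. With the striatal level as a covariate the mean log2 difference was -0.38 (SE 0.23 over libraries, camera adjusted p = 1.2e-07, and p = 0.17 with an estimated correlation). Without control 2 and isolated 3 it was -0.41 (camera adjusted p = 0.00039, and p = 0.35 with an estimated correlation). Both lie near the -0.42 of all 6 libraries, but the spread with the covariate is too wide to exclude a fall to under 0.5 of the value. The level of the single library control 1 is a candidate explanation for part of the difference: without this library the mean was -0.21 in place of -0.42 (camera adjusted p = 0.057, and p = 0.46 with an estimated correlation). Control 1 was the highest control, so leaving it out had to shrink the difference. Without control 3, the lowest control, the mean was -0.6 (camera p = 0.027 with an estimated correlation, not adjusted over the lists). The time from handling to death, which these genes follow within minutes, is not in the labels and was not tested.

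The numbers of genes and lists called were also counted over the 10 splits of the 6 libraries, which are too few for a share under 0.05. The real split called 0 genes with edgeR (535 at an unadjusted p under 0.05; DESeq2 called 1 and limma-voom 0) and the highest other 0. A count of 0 is reached by 10 of 10 splits whatever the data, so this comparison carries no information. For lists the real split called 10 and the highest other 12, and 3 of 10 gave as many. Control 1, control 2 and isolated 3 against the rest had 2513 genes at an unadjusted p under 0.05, which points to a structure of the samples that crosses the groups. These libraries also had the highest mean log2 CPM of the striatal list. It was 5.58, 7.26 and 6.82 in them, against 3.47 in control 3, 4.53 in isolated 1 and 4.45 in isolated 2.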
